A study of Mus musculus with 2 samples.

How the data were processed

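CUT&Tag libraries of HpNSC, a mouse neural stem cell line, were compared between an antibody against the glucocorticoid receptor (GR) and a control IgG. In CUT&Tag an antibody on permeabilised cells directs the Tn5 transposase to cut and tag the DNA beside the bound protein, and the tagged fragments are sequenced. Per the labels' protocols, 100000 cells were used, and the treatment was 1 µM dexamethasone (Dex), a synthetic GR ligand, for 3 days with 20 ng/ml FGF2. The growth protocol gives 20 ng/ml each of EGF and FGF2. The GR group and the IgG group each held 1 library, and the labels give the same treatment for both. No untreated library and no replicate was analysed here, so no test between conditions, no p-value and no standard deviation is given.

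Each library came as a list of peaks. Trim Galore 0.6.7, MACS2 2.1.4 and deepTools are named in the submitters' processing notes, as is the genome build mm10. The aligner, the filters on duplicates and mapping quality, and the caller's settings are not given in the sources used here. The deposited fold column holds the ratio of the fragment coverage to the local background at the summit, the position of highest coverage in the peak. As solved below, a pseudocount of 1 is added to both, which lowers the fold most where the background is far below 1. The deposited significance columns hold −log10 p and −log10 q per peak. The deposited score column was used in no comparison. These values are the authors' own and were used to describe, rank or filter peaks within a list. Peaks were called per library. The highest q in the GR list was 0.0496 and the highest in the IgG list was 0.0407, so both lists lie under a q of 0.05.

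The number of fragments covering each summit and the local background were recovered from the deposited values by solving the fold, with the caller's pseudocount of 1 in numerator and denominator, together with the Poisson −log10 p. A single whole number of fragments solved all 21705 GR peaks and all 2067 IgG peaks, with a largest misfit of 0.00082 in −log10 p. Fragment counts carry exact Poisson 95% intervals and shares carry exact Clopper-Pearson 95% intervals. Both cover counting error at most. If PCR copies were kept, the fragments are not independent molecules and the fragment intervals are too narrow. Library totals are not given in the lists. The backgrounds lay on steps of 0.0268 per fragment in the GR list and 0.0103 in the IgG list. If the caller's window was 10 kb, the smallest background was 7.69 fragments per 10 kb in the GR list and 2.0 in the IgG list. On that reading the IgG library was the shallower one by at least 3.85 times, and a peak of 2 fragments sufficed for a call in it.

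Genes came from a RefSeq table of GRCm38.p6, the same build as mm10, with 21887 protein-coding genes on chromosomes 1 to 19, X and Y. The table gives gene spans and no strand, exons or sequence. Positions are therefore given relative to the lower-coordinate or upper-coordinate end of a gene, and neither end is called the promoter. Peaks were classed as gene end (summit within 1 kb of either end of a protein-coding gene), gene interior or between genes. This replaced the planned classes around transcription start sites, exons and introns. The planned search for GR sequence motifs needs the genome sequence and was not run.

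A GR peak sharing at least 1 bp with an IgG peak counted as shared. The remaining peaks on chromosomes 1 to 19, X and Y are called GR-only. Chance levels came from placing each list at random on the same chromosomes 100 times with bedtools 2.31.1. A gene was occupied at its end or in its locus when a GR-only summit lay within 1 kb or 25 kb of either end. For 15 gene lists the occupied share, and the median over genes of the highest −log10 q within 25 kb (0 for a gene without a peak), were placed among 10000 random lists of as many protein-coding genes, matched on decile of gene length. Matching on CpG content, planned for gene ends, was replaced by this. These percentiles describe the 2 libraries only. All 267 listed symbols, 256 different genes, were found in the table.

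The lists, the thresholds and the rule for named genes were fixed before the data were examined. The rule named Ascl1 and Nr3c1, up to 4 members per list with the highest −log10 q of a GR-only peak within 25 kb, and the genes nearest to the 10 GR-only peaks of highest fold and to the 10 gene-end peaks of highest −log10 q. A part of the rule that needed motif matches was not applied. Genes named outside the rule are said to be so. The alternatives were −log10 q of at least 5 or 10, a fold of at least 5, autosomes only, other definitions of a shared peak, gene-end and locus distances, inclusion of shared peaks and unmatched random lists. Others were added after the data were seen.

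Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. On simulated values the fragment number was recovered for 100% of 1000 peaks drawn from the GR list and 99.8% of 1000 drawn from the IgG list. Of overlaps planted among the 21206 autosomal GR peaks, all 150 were found. These were peaks kept at their own positions, so only the counting was checked. A simulated list of 20 genes, 15 of them occupied, reached the 100.0 percentile among 20665 autosomal genes, and 0 of 100 random lists passed the 97.5 percentile. Peaks on the mitochondrial genome and on unplaced scaffolds were left out of the comparisons with genes.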

Results

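Binding of GR, the nuclear receptor for glucocorticoids, was profiled across the mouse genome (mm10) in HpNSC neural stem cells given Dex, with IgG as the control. The series concerns stress, stem cell quiescence and repression of Ascl1, a proneural transcription factor. The GR library gave 21705 peaks with a median width of 479 bp, and the IgG library gave 2067 peaks with a median width of 176 bp. The median GR peak had 10 fragments at its summit (interquartile range 6 to 17) and a fold of 5.62. The median IgG peak had 2 fragments and a fold of 2.94. The median local background was 0.870 in the GR list and 0.0308 in the IgG list. With the pseudocount of 1, a peak on so low a background as in the IgG list has its fold set mainly by its fragment number. These folds therefore do not compare enrichment between the lists. Among IgG peaks 65.5% (95% CI 63.4 to 67.6) rested on 2 fragments, whereas 53.2% of GR peaks had at least 10. Each antibody had 1 library, so no difference between them has a replicate check. The number of peaks per list also depends on depth, which was lower for IgG as far as the smallest backgrounds show it.

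**Figure D1:**
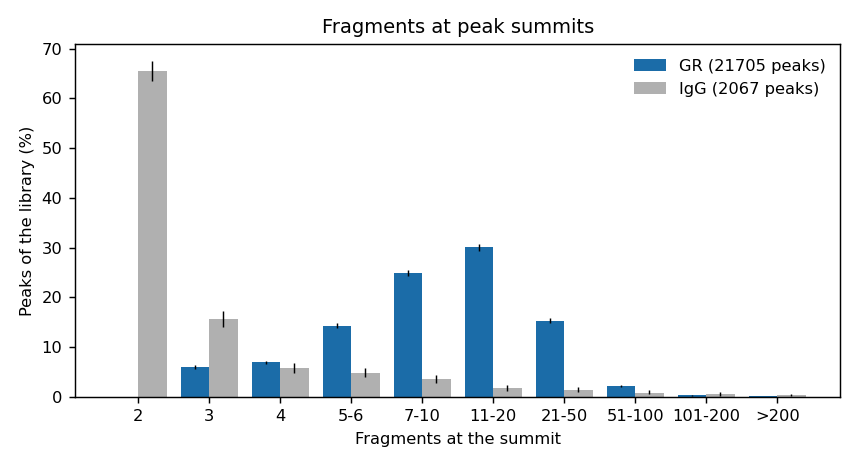
Percentage of peaks of each library (vertical axis) by the number of fragments at the summit (horizontal axis), for the GR library and the IgG library, with exact 95% binomial intervals as error bars. IgG peaks lie mostly at 2 fragments (65.5%), and the fullest GR class is 11 to 20 fragments (30.0%).

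Few GR peaks coincided with an IgG peak. Of 21705 GR peaks, 201 (0.926%, 95% CI 0.803 to 1.06) shared at least 1 bp with an IgG peak. On chromosomes 1 to 19, X and Y the count was 198, against a mean of 12.1 (3 to 24) when GR peaks were placed at random, 16.3 times as many. From the other side, 204 IgG peaks (9.87%, 8.62 to 11.2) met a GR peak. Shared GR peaks were taller than GR-only peaks, with a median of 20 fragments against 10. On these chromosomes the share of GR peaks with an IgG overlap was 0.214% (0.0787 to 0.466) at 3 to 4 fragments, 1.51% (1.12 to 1.98) at 21 to 50, and 66.7% (47.2 to 82.7) of the 30 peaks with over 200 fragments. The overall share was 0.436% when both lists were held to a −log10 q of at least 5.

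GR-only peaks lay at gene ends far more often than random positions. Of 21479 GR-only peaks, 31.4% (30.7 to 32.0) had their summit within 1 kb of an end of a protein-coding gene, against 2.92% (2.70 to 3.28) under random placement, a ratio of 10.7. A further 39.3% (38.7 to 39.97) lay inside genes, against 36.8% at random, and 29.3% (28.7 to 30.0) lay between genes, against 60.3%. IgG peaks that met no GR peak lay at gene ends in 6.49% (5.41 to 7.72) of cases, 2.21 times the random share. IgG peaks that met a GR peak did so in 53.0% (45.8 to 60.1). Gene-end GR-only peaks had a median of 13 fragments, compared with 9 inside genes and 8 between genes. Over all GR peaks on these chromosomes the gene-end share followed peak height up to a point, from 7.68% (6.72 to 8.73) at 3 to 4 fragments to 43.3% (41.6 to 45.0) at 21 to 50, and was 6.67% (0.818 to 22.1) among the 30 tallest peaks. In all, 7556 of 21887 protein-coding genes (34.5%) had a GR-only peak at an end and 13964 (63.8%) had one within 25 kb. The IgG list marked 270 genes (1.23%) and 1777 genes (8.12%) by the same distances.

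**Figure D2:**
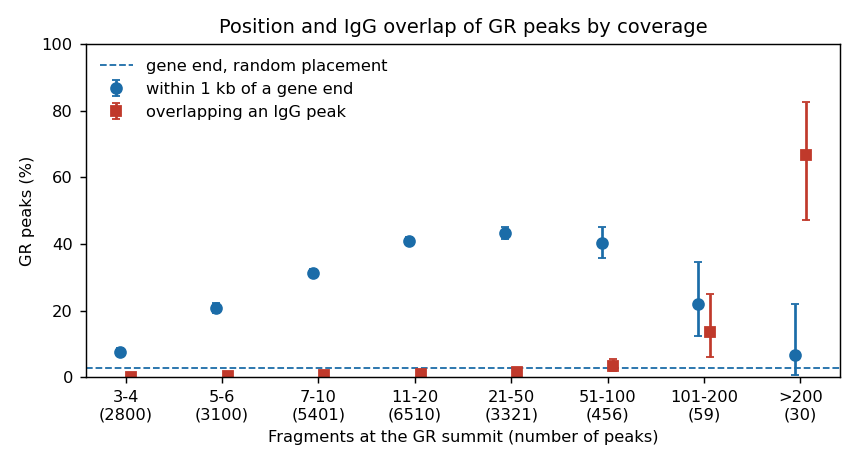
Percentage of GR peaks on chromosomes 1 to 19, X and Y (vertical axis) that lie within 1 kb of a gene end (circles) or overlap an IgG peak (squares), by fragments at the summit (horizontal axis, number of peaks in parentheses), with exact 95% binomial intervals. The dashed line is the mean gene-end share of randomly placed peaks (2.92%), and the gene-end share is highest at 21 to 50 fragments (43.3%).

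Genes known to be induced by glucocorticoids carried many GR peaks, and strong ones by −log10 q. Of 29 such genes, 28 (96.6%, 82.2 to 99.9) had a GR-only peak within 25 kb, the exception being Cdkn1c (named here only for that value), and 17 (58.6%, 38.9 to 76.5) had one at a gene end. These shares lay at the 100 and 99.8 percentiles of length-matched random lists. The median over the list of the strongest −log10 q was 18.7, against 4.29 (0.0 to 8.62) for random lists. The strongest peak belonged to Per1, a clock gene with glucocorticoid response elements. It lay inside the gene at chromosome 11, 69096611 to 69097697, and reached 324 fragments (95% CI 290 to 361) over a background of 47.3, with a −log10 q of 148. Per1 had 7 GR-only peaks within 25 kb. Hif3a, an oxygen-sensing factor, had an internal peak of 184 fragments (158 to 213). The metallothionein genes Mt1 and Mt2, which bind heavy metals, shared a peak of 115 fragments (94.9 to 138) at chromosome 8, 94189207 to 94190056, 9.33 kb beyond Mt1. Fkbp5, the co-chaperone that lowers the affinity of GR for its ligand, had an internal peak of 62 fragments (47.5 to 79.5) at chromosome 17, 28419765 to 28420853, and 4 peaks within 25 kb of its ends. By fold the Per1 peak was less extreme, with 6.73, rank 6806 of 21705 GR peaks. Its local background of 47.3 was high, against a median of 0.870 over GR peaks, and peaks of 193 and 85 fragments lay on either side. The rank by fold reflects that background as well as the height of the Per1 peak. Folds were 7.79 at the Hif3a peak, 13.0 at that of Mt1 and Mt2 and 10.1 at that of Fkbp5. IgG peaks marked 0 of the 29 genes at their ends and 4 within 25 kb.

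Circadian clock genes were likewise widely occupied. All 16 (100%, 79.4 to 100) had a GR-only peak within 25 kb and 14 (87.5%, 61.7 to 98.5) had one at a gene end, at the 99.9 and 100 percentiles. The former was 86.6 when random lists were also matched on having a gene-end peak, a matching added after the data were seen. The median strongest −log10 q was 22.2, against 5.60 (0.0 to 11.3) for random lists. Besides Per1, the only gene on both lists, the members with the strongest peaks were Tef with 149 fragments (126 to 175), Bhlhe40 with 66 (51.0 to 84.0) and Per2 with 57 (43.2 to 73.9). The Bhlhe40 peak lay 0.317 kb outside the gene, and those of Tef and Per2 lay inside the genes.

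Housekeeping genes were also widely occupied. Of 20, 15 (75%, 50.9 to 91.3) had a gene-end peak, at the 99.98 percentile, and 19 had one within 25 kb, at the 99.9 percentile (91.2 under the same added matching). Their peaks were lower, with a median strongest −log10 q of 10.5 at the 97.47 percentile. Examples were Polr2a, a subunit of RNA polymerase II, with 42 fragments (30.3 to 56.8), and Rps18, a ribosomal protein gene, with 40 (28.6 to 54.5). Hmbs also had 40, at a peak 1.59 kb outside the gene, while Eef1a1 had 42.

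Among stem cell genes, those of activation, quiescence and identity were all occupied above most random lists at the 25 kb distance. For activation and cell cycle entry, 19 of 20 genes (95%, 75.1 to 99.9) had a peak within 25 kb, at the 99.8 percentile, and 11 had one at a gene end, at the 95.7 percentile. The kinases Cdk2 and Cdk4 had peaks of 60 (45.8 to 77.2) and 49 (36.3 to 64.8) fragments, that of Cdk2 1.68 kb outside the gene. The strongest peak of E2f1, a regulator of S-phase genes, had 43 (31.1 to 57.9) and lay 15.4 kb outside the gene. Pcna, the replication clamp, had an internal peak of 33 (22.7 to 46.3). With only peaks of −log10 q of at least 10, the percentile of this list within 25 kb was 79.4. For quiescence, Notch and BMP genes, 24 of 28 (85.7%, 67.3 to 96.0) had a peak within 25 kb, at the 99.3 percentile, and 11 had one at a gene end, at the 70.6 percentile. The highest peaks there were near Apoe with 65 fragments (50.2 to 82.8) and in Notch1 with 71 (55.5 to 89.6), then at the Notch effector Hes5 with 52 (38.8 to 68.2) and at the cell cycle inhibitor gene Cdkn1b with 53 (39.7 to 69.3). The Apoe peak lay 14.6 kb and the Hes5 peak 12.0 kb outside the gene. For stem cell identity, 13 of 17 genes (76.5%, 50.1 to 93.2) had a gene-end peak and 15 had a peak within 25 kb, at the 99.95 and 97.53 percentiles. The latter was 36.9 under the matching on a gene-end peak and 95.8 on autosomes alone. The former was 94.5 at a fold of at least 5. Fabp7, a radial glia gene, had 61 fragments (46.7 to 78.4), Gfap had 50 (37.1 to 65.9) and Sox21 had 40. The Gfap and Sox21 peaks lay 1.42 and 2.73 kb outside the genes. Sox9 had 28, at a peak 23.7 kb outside the gene.

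Astrocyte genes stood out by peak strength. Of 12, 11 had a peak within 25 kb, at the 96.5 percentile, and 7 had one at a gene end, at the 93.0 percentile, while the median strongest −log10 q of 18.5 lay at the 99.9 percentile. The highest were near Aldh1l1, a folate enzyme gene, with 84 fragments (67.0 to 104) and near Atp1b2 with 71 (55.5 to 89.6). The glutamate transporter gene Slc1a2 had 36, at a peak 22.2 kb outside the gene. For the oligodendrocyte lineage, 10 of 12 genes had a peak within 25 kb, at the 85.6 percentile, and 2 had one at a gene end, at the 6.65 percentile (0 of 12 and 0.67 at a fold of at least 5). Olig1 had 72 fragments (56.3 to 90.7), Cspg4 had 44, Myrf had 42 and Olig2 had 34. The Olig1, Myrf and Olig2 peaks lay 6.6, 19.7 and 4.9 kb outside the genes. For neuronal genes, 11 of 19 had a peak within 25 kb and 4 had one at a gene end, at the 18.2 and 8.26 percentiles. Elavl3 had 28 fragments, Sox11 had 29, Tubb3 had 15 and Calb2 had 12. The Elavl3, Tubb3 and Calb2 peaks lay 12.1, 21.1 and 6.05 kb outside the genes.

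The receptor, its chaperones and the stress axis had peaks within 25 kb at 15 of 18 genes and at the gene ends of 7, at the 93.3 and 62.3 percentiles. The chaperone gene Hspa8 had 63 fragments (48.4 to 80.6), Hsp90ab1 had 51 (38.0 to 67.1) and the coactivator gene Ncoa1 had 34. The Hsp90ab1 and Ncoa1 peaks lay 11.6 and 13.3 kb outside the genes. For growth factor and Wnt signalling, 17 of 22 genes had a peak within 25 kb and 6 had one at a gene end, at the 72.5 and 13.6 percentiles. Fgf2 had 45 fragments (32.8 to 60.2), Ptch1 had 46, Dusp6 had 44 and Gli1 had 27. The Fgf2 and Gli1 peaks lay 9.88 and 17.6 kb outside the genes.

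Microglial, endothelial and hepatocyte genes had few gene-end peaks, and so had inflammatory genes known to be repressed by glucocorticoids, while the counts within 25 kb varied. Of 15 repressed inflammatory genes, 7 had a peak within 25 kb and 2 had one at a gene end, at the 9.12 and 4.04 percentiles. With only peaks of −log10 q of at least 5, 2 had a peak within 25 kb and 0 had one at a gene end, at the 0.21 and 0.56 percentiles. Their peaks were low, with 10 fragments (4.8 to 18.4) near Il1a, 9 near Cxcl10 and near Mmp9, and 5 at Il11. Microglial genes had a peak within 25 kb in 4 of 12 cases and at a gene end in 1, at the 0.92 and 1.82 percentiles. These were Aif1 with 64 fragments, Spi1 with 36, Tmem119 with 15 and Ptprc with 3. The Aif1, Spi1 and Tmem119 peaks lay 5.86, 12.1 and 13.2 kb outside the genes. The percentile within 25 kb was 32.9 with only peaks of −log10 q of at least 10. Endothelial and mural genes had 9 of 12 and 1 of 12, at the 73.2 and 2.07 percentiles, with 21 fragments at Pecam1 and at most 14 near Tie1, Vtn and Cdh5. Within 25 kb the endothelial placing ranged from 5.08 with only peaks of −log10 q of at least 10 to 94.6 under the matching on a gene-end peak. Hepatocyte genes that respond to glucocorticoids had 9 of 15 and 1 of 15, at the 27.0 and 0.46 percentiles, with 19 fragments near Hp, 18 near G6pc, 14 at Ttr and 12 near Pck1. At gene ends the low placings of the endothelial and hepatocyte lists rose to at most 10.9 and 5.09 under other settings. A peak within 25 kb of one gene can lie nearer to another, and no expression was measured here.

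**Figure D3:**
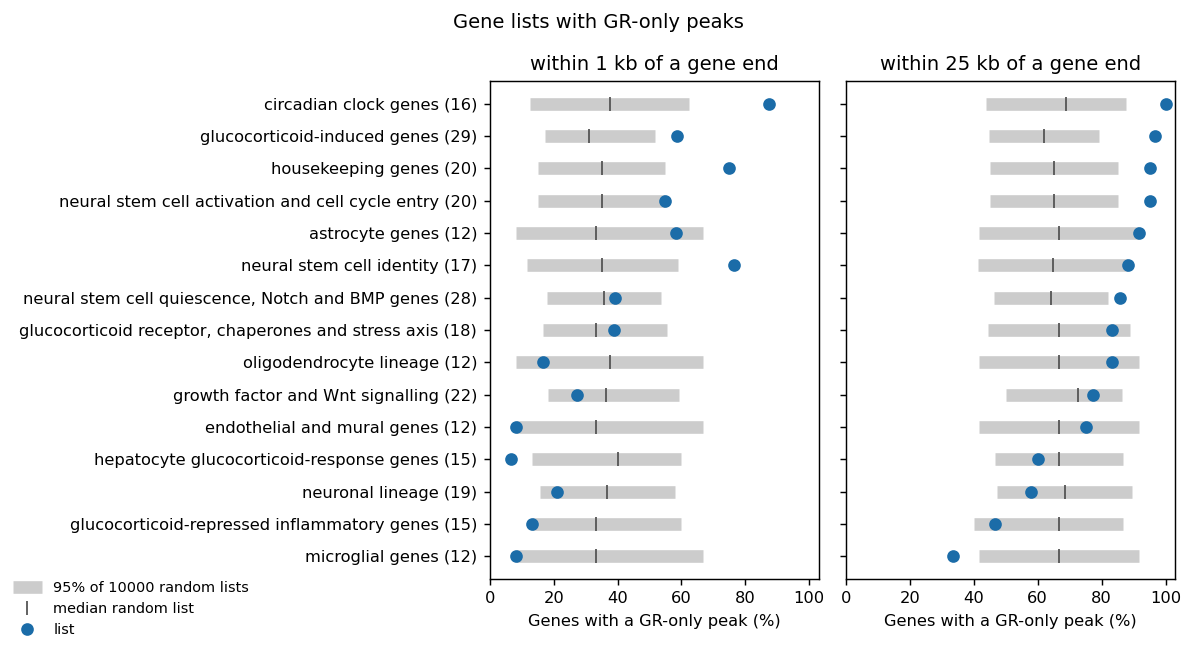
Percentage of the genes of each list (number of genes in parentheses) with a GR-only peak within 1 kb (left) or 25 kb (right) of a gene end. Points are the lists, grey bars hold 95% of 10000 length-matched random lists and ticks are their medians. Circadian genes (87.5% and 100%) and glucocorticoid-induced genes (58.6% and 96.6%) lie to the right of both bars, as do housekeeping genes.

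At Ascl1, chromosome 10, 87490819 to 87493660, a GR peak of moderate height lay just outside the gene. It spanned 87489620 to 87490248, with its summit 0.781 kb below the lower end, in the gene-end class. It had 20 fragments (95% CI 12.2 to 30.9) over a background of 4.03, a fold of 4.18 and a −log10 q of 5.65, rank 10623 of 21705. Of the 6734 gene-end GR-only peaks, 74.2% had fewer fragments, 37.8% a lower −log10 q and 9.79% a lower fold. A second GR peak, 42.9 kb below the gene at 87447737 to 87448211, was more enriched, with 25 fragments (16.2 to 36.9), a fold of 10.6, a −log10 q of 19.2 and rank 1699. No other GR peak lay within 100 kb of the gene, and 0 IgG peaks lay within 250 kb. The IgG list marked only 8.12% of protein-coding genes within 25 kb, so this absence says little. The nearer peak passed a −log10 q of 5 but neither a −log10 q of 10 nor a fold of 5. At Nr3c1, which encodes GR (chromosome 18, 39410545 to 39519421), 0 GR-only peaks lay within 25 kb of an end, and 1 lay inside the gene, 28.0 kb from the upper end, with 26 fragments (17.0 to 38.1) and a −log10 q of 15.4.

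**Figure D4:**
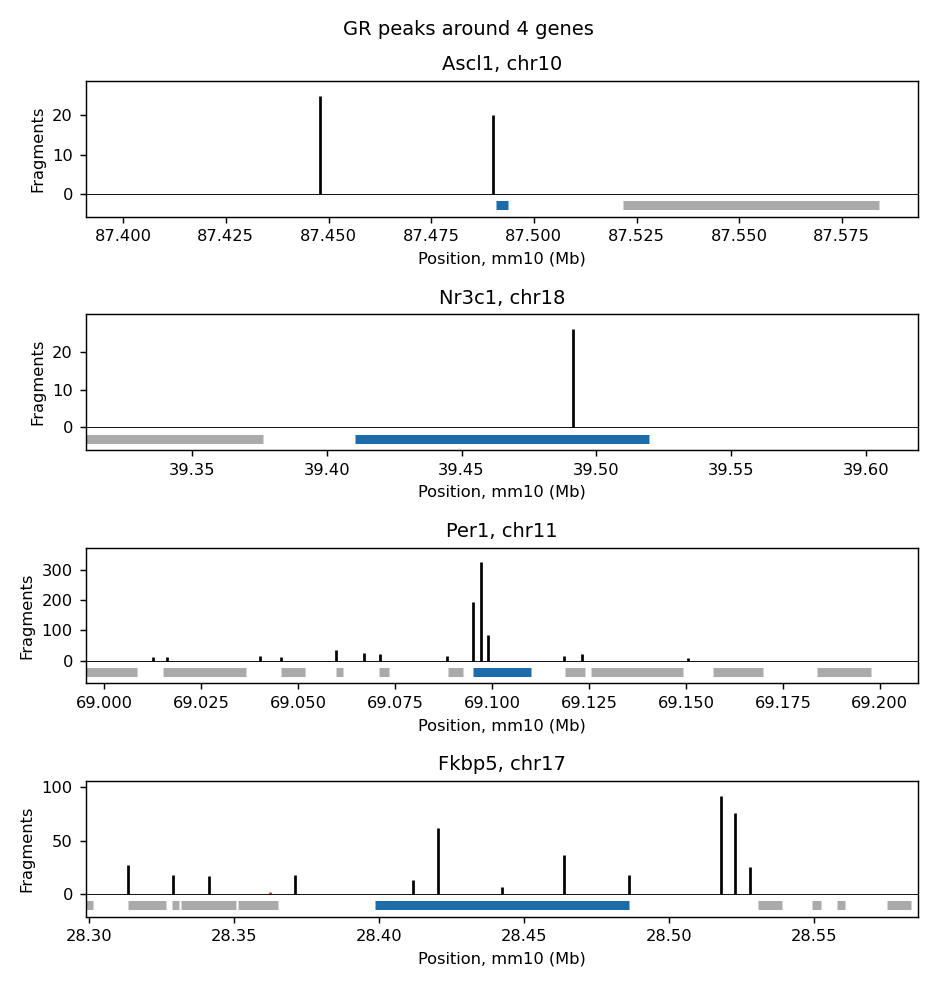
GR peaks (black lines at the summits, height in fragments) and IgG peaks (red) from 100 kb below to 100 kb above Ascl1, Nr3c1, Per1 and Fkbp5, by position on mm10 in Mb. Blue bars are the named genes and grey bars other protein-coding genes. Ascl1 has 2 GR peaks in its window and Nr3c1 has 1, compared with 14 at Per1 and 12 at Fkbp5, and the vertical scales differ.

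By −log10 q, the 10 highest gene-end GR-only peaks lay at genes outside the lists. The first, at Lars2, was 390 bp wide, with 406 fragments (367 to 447) and a fold of 26.5. It was among the 9 GR-only peaks narrower than 400 bp with at least 100 fragments, of 61 with that coverage. Next came Zbtb20, a transcription factor of hippocampal development, with 173 fragments (148 to 201), and Ndrg2 with 150 (127 to 176). Mid1 had 165 (141 to 192) and Cryzl1 had 130 (109 to 154). Hnrnpul2, Rap2a, Rab40c, Srp54b and Usp5 followed with 93 to 125 fragments. A gene-end peak of Per1 had 193 fragments, a fold of 4.06 and a lower −log10 q of 52.5. The 10 GR-only peaks of highest fold were 302 to 548 bp wide, with 129 to 434 fragments and folds of 22.0 to 29.2. The nearest genes were Gphn, Camk1d, Lars2, Arhgap21, Serpina3n, Filip1l, Cdk8, Ppp1r9a, Nkx2-6 and Cr2, and only the Lars2 peak lay within 1 kb of a gene end. Of the 50 GR peaks of highest fold, 20 overlapped an IgG peak, against 0.926% of all GR peaks, and 6 lay at a gene end. Their median width was 421 bp, against 930 bp for GR peaks of 101 to 200 fragments. Of the 50 of highest −log10 q, 25 overlapped an IgG peak. The IgG library appeared shallow, so the lack of an IgG overlap does not show that the peaks named here depend on the GR antibody.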

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

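The mitochondrial genome and the unplaced scaffolds, which entered no comparison with genes, held more GR peaks than IgG peaks. The mitochondrial genome had 5 GR peaks, covering 10400 bp with up to 2458 fragments at a summit and folds of 1.34 to 3.53. In the IgG list it had 3 peaks, covering 1220 bp with up to 36 fragments and folds of 5.77 to 7.71. The scaffolds had 23 GR peaks with up to 155 fragments and 16 IgG peaks with up to 96 fragments. As far as the smallest backgrounds show it, the IgG library was shallower, which bears on each of these counts.

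The test of IgG depth was chosen after the overlap had been seen, and the matchings on gene density and on gene-end peaks were added after the data were seen, before their outcomes were known. The first pattern weighed is the small overlap of GR with IgG peaks. If the IgG library held the same relative profile as GR, thinned to its own depth, the number of GR peaks expected to reach 2 IgG fragments depends on that depth, which the list only bounds. The highest depth was set by the smallest backgrounds, as an IgG to GR coverage ratio of 0.0996. That ratio is of coverage, whereas the 3.85 times given above is of fragments. At the lowest depth the list allows, 55.7 such peaks were expected, and at the highest 7405, while 201 were observed (upper 95% limit 231). A signal specific to the GR antibody and a shallow control therefore cannot be told apart, because the IgG total is not in the list.

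The second pattern is the strength of peaks at glucocorticoid-induced and circadian genes. Dense gene neighbourhoods were argued against: among random lists matched on the number of genes within 100 kb, the lower of the 2 percentiles of the median strongest −log10 q was 100. Accessible gene ends, as far as a GR-only gene-end peak marks them, were argued against as well: among random lists matched on gene length and on such a peak, the lower percentile was 99.96, whereas housekeeping and stem cell identity genes came to 68.9 and 79.8. Astrocyte genes and quiescence, Notch and BMP genes also stayed high, at 99.8 and 99.7, so the strength was not particular to these 2 lists. Some genes, named here only for that, are on more than 1 list, so the lists are not independent. Glul is on the glucocorticoid-induced and astrocyte lists, and Cdkn1a and Cdkn1c are on the glucocorticoid-induced and quiescence lists. Aldoc is on the astrocyte and quiescence lists. Differences in the degree of openness among gene ends with a peak stay open, since no accessibility was measured. Binding of the ligand-activated receptor is a biological hypothesis that also stays open, untested without an untreated library or a GR-deficient control.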

How the results depend on the processing

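The settings on summit coverage, gene density, gene-end matching, whole gene spans and narrow peaks were chosen after seeing the data. Counts fell with stricter calling, by construction: 11916 GR and 257 IgG peaks had a −log10 q of at least 5, 5220 and 117 at least 10, and 13477 and 266 a fold of at least 5. The share of GR peaks overlapping IgG was 0.436%, 0.498% and 0.349% at these settings, 0.189% when at least 50% of the GR peak had to be covered, 0.613% for summits within 200 bp, 1.31% within 1 kb, 0.507% with IgG peaks of at least 3 fragments and 1.45% for GR peaks of at least 10 fragments. The gene-end share was 39.5% and 43.3% at the stricter −log10 q settings, 38.2% at a fold of at least 5, 40.6% at 10 or more fragments, 38.3% within 3 kb and 36.6% with the ends of every annotated gene. The Ascl1 window held 1 peak at a −log10 q of at least 10 and 1 at a fold of at least 5. The causes of the moved shares were not tested. Within 25 kb, 6 of 15 lists lay in the top 2.5% of random lists, and 3 did so when random lists were matched on gene length and a gene-end peak. Of 495 recomputed list percentiles, 438 stayed in the same band (top 2.5%, bottom 2.5% or between), 57 moved to a neighbouring one and 0 went from one extreme to the other. The glucocorticoid-induced list was in the top 2.5% in all 12 settings within 25 kb and by strongest peak, and in all 9 at gene ends. The circadian list did so in 11 of 12, 12 of 12 and 9 of 9, with 86.6 within 25 kb under gene-end matching. Activation genes were in the top 2.5% within 25 kb in 8 of 12 settings, quiescence genes in 12 of 12 and identity genes in 8 of 12. Housekeeping genes were so in 11 of 12, with 91.2 under gene-end matching, and astrocyte genes in 7 of 12. In the bottom 2.5% were repressed inflammatory genes in 4 of 12 settings within 25 kb and 3 of 9 at gene ends, microglial genes in 8 of 12 settings within 25 kb and 7 of 9 at gene ends, endothelial and hepatocyte genes each in 5 of 9 and oligodendrocyte genes in 1 of 9 at gene ends. The motif settings were not run, and the protein-coding restriction was already in place. No paired analysis was possible because each antibody had 1 library. The depth of the IgG library, known only within bounds, limits what its list can show.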

Other observations

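The gene families, chromosomes and genes here and the test on the interferon zeta array were chosen after the data were seen. Some gene families, picked with their counts in view, are given with their gene-end GR-only peaks and their percentiles among length-matched random lists, which do not allow for neighbouring genes that share a peak. Replication histone genes, which lie in clusters, had such peaks in 46 of 58 cases (79.3%, 95% CI 66.7 to 88.8). The random median was 10.3% for genes of these lengths, and the share over all protein-coding genes was 34.5%. Complex I genes had them in 41 of 49, proteasome genes in 39 of 51, mitochondrial ribosomal protein genes in 54 of 78 and genes with cytosolic ribosomal protein symbols in 64 of 99, each at the 100 percentile. The families were picked by symbol, so membership is approximate. The complex I pattern also admits Ndufaf assembly factor genes, and the cytosolic ribosomal pattern also admits Rps6k kinase genes. Olfactory receptor genes had 1 of 1110, vomeronasal receptor genes 2 of 355, keratins 0 of 53 (which allows up to 6.72%), serpins 6 of 63, protocadherins 7 of 69 and Hox genes 1 of 39, each at the 0.0 percentile. Zinc finger genes named Zfp had 190 of 397 at the 99.99 percentile, Kruppel-like factor genes 9 of 17 at the 91.3 and Sox genes 8 of 19 at the 80.0. Nuclear receptor genes with an Nr symbol, which leaves out receptors named otherwise, had 9 of 26 at the 39.6.

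On the X chromosome 188 of 966 protein-coding genes (19.5%, 17.0 to 22.1) had a gene-end peak, against 35.7% (35.0 to 36.3) on the autosomes, and the median gene-end peak had 9 fragments against 13. The X held 2.13% of GR-only peaks and 4.49% of IgG peaks. Genes with the most GR-only peaks in their span and 25 kb around it were Msi2 with 24, Nfia with 22 and Gse1 with 20, which span 379, 541 and 353 kb.

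A short stretch of chromosome 4, 88754868 to 88808380, holds an array of 15 interferon zeta genes, and 15 GR-only peaks lay on it with a median spacing of 2.92 kb. They had 15 to 41 fragments and folds of 2.88 to 5.10, over a median background of 7.58, which was 36.8 times the smallest in the GR list. No IgG peak lay there, which says little because the IgG list held only 2067 peaks. Reads shared between near-identical gene copies may spread coverage evenly over such an array. The variance of the 15 fragment counts over their mean was 1.92 (1.03 to 4.77), where counting error alone gives up to 1.87 and 49 of 1422 runs of as many neighbouring peaks elsewhere were as even. The bound that would argue against shared reads was widened to the lower limit of this interval after the value was seen. Shared reads and separate sites cannot be told apart by this value, and no biological explanation was tested.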
